A study of Arabidopsis thaliana with 12 samples.

How the data were processed

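RNA was sequenced from rosette leaves of Arabidopsis thaliana, ecotype Col-0, in 12 samples. Plants were grown on soil at 23 °C for 3 weeks, and the heated ones were then kept at 47 °C for 1 h, per the labels' protocols. Wild type (WT) and the mutant atcyp18-2 were each sampled with and without heat, which gives 4 groups of 3 samples. Group and replicate number were read from the sample titles. Headers of the count columns give hours without saying when the controls were harvested, and no sample kept at 23 °C for that hour is named. If the controls were taken before that hour, heat and the passing of 1 h cannot be told apart. Nothing in the labels says that the replicates came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

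The deposited series table holds whole-number counts under a header that calls them raw data, per the file headers. HTSeq and DESeq are named in the submitters' processing notes without a version or a role. The aligner, the genome build and the annotation release are not given in the sources used here, beyond a header that names Phytozome as the source of the annotation. The table has 51792 rows, each a transcript, and 8624 of them are assembled transcripts without a locus identifier of their own. The lowest value in any library was 1 and no row was at 1 in all 12 libraries, while 1573 rows had 1 library at 2 and the others at 1. The deposited counts therefore carry 1 added read per row, and read numbers printed here have it subtracted. In the deposited table a read that fits several transcripts of a gene appears to be counted for each of them, since the median transcript of the 12692 genes with several held 100.0% of the total of the largest one. The counts thus cannot be summed over transcripts. For each of the 23174 genes the annotated transcript with the highest total over all libraries was used, 23160 genes having one, and the highest assembled transcript for the rest. The design fixed beforehand had assumed counts per gene. It was kept, with these counts per transcript in their place. The choice of transcript and the added read were varied, as alternatives chosen after seeing the data. No protocol states that counting used strand, so reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

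The authors also deposited 4 lists of changed genes, with a log2 fold change and an adjusted p-value for each gene, and every gene in them had an absolute log2 fold change of at least 1.00 and an adjusted p-value of at most 0.01, per the file values. These lists were used only for a comparison of gene names and directions. The 12 columns of the authors' normalized values in the series table were not used, nor were the authors' tables of enriched terms. Splicing, which the series title names, was not analysed here.

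Gene symbols were taken from the RefSeq gene table of assembly TAIR10.1, in which 22965 of the 23174 identifiers were found. The others are named by their identifier. Since no build is named with the counts, no coordinates are given. Libraries held 9075387 to 12493977 reads with 1 transcript per gene, of which 2572364 to 4348395 were from nuclear genes. Within a group, the lowest chi-square per degree of freedom between any pair of libraries was 2.25, so no pair agreed within sampling noise and each library was counted as 1 sample.

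Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and filterByExpr by group, in 1 fit of all 12 libraries with a coefficient per group. This fit kept 16636 genes, had 8 residual degrees of freedom and gave a common biological coefficient of variation of 0.231. The 5 contrasts were heat in WT, heat in atcyp18-2, the mutant against WT without heat, the mutant against WT after heat, and the difference of the heat response between genotypes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. CPM values are counts relative to the library total as scaled by TMM, and include the added read. The standard error of a log2 fold change was taken as its size over the root of the quasi-likelihood F. Where a group had 0 reads over its 3 libraries, the fold is a bound computed against 3 reads over the group. With 1 to 3 reads it is a ratio with a 95% exact binomial interval, and both cover counting error only.

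Before the data were examined, 23 gene lists were fixed: small heat shock proteins, HSP70, HSP90, HSP100 and HSP60 chaperones, co-chaperones, heat shock factors, endoplasmic reticulum protein folding, oxidative stress, abscisic acid and dehydration, jasmonate and wounding, salicylic acid and defence, rapid touch, cold and ethylene response, photosynthesis, auxin response, expansins and xyloglucan endotransglucosylases, SR splicing factors, other splicing factors, other cyclophilins, circadian clock, glucosinolate biosynthesis, flavonoid and anthocyanin biosynthesis, dividing cells, guard cells, root, and flower and seed. The 21 lists with at least 3 fitted members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation, camera with the replicate number as a block and fry were the alternatives. The genes named in the text were also chosen by a rule fixed then. The mutated gene comes first. Then come up to 10 genes with the largest increase and 10 with the largest decrease among called genes with a mean of at least 10 CPM and no overlap between the groups' replicates. For the difference of the heat response the overlap was not considered and the mean was over all samples. From each list the 2 called members with the largest change and the most abundant member, called or not, follow, and lists without a called member are given as counts. Genes named outside this rule are marked in the text.

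The tests were checked on simulated counts for the 16636 genes with 100 genes changed by a fold of 4 and 100 by a fold of 2. For the 4 comparisons between groups, in the order given above, the edgeR test recovered 83, 76, 91 and 80 of the former and 23, 22, 28 and 21 of the latter, with 8, 5, 9 and 5 false calls. DESeq2 1.42.0 recovered 84, 88, 90 and 82 and then 36, 35, 40 and 36, with 25, 24, 25 and 19 false calls. The difference of the heat response was not simulated. Simulated genes varied independently of each other, without the library component described below, so these numbers may not hold for the real libraries. The alternatives fixed beforehand were DESeq2, RLE size factors, library totals, no filter on low counts, a filter at 10 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block, stricter thresholds, removal of chloroplast and mitochondrial genes, and each library left out in turn. After the data were seen, 1 surrogate variable (sva 3.50.0) and fits restricted to libraries on 1 side of a library component were added. Exon sequences of TAIR10.1 were used only for base composition and length. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.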

Results

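Transcript levels were measured by RNA-seq in rosette leaves of 3-week-old Arabidopsis thaliana (ecotype Col-0), in wild type (WT) and in atcyp18-2, a mutant of the cyclophilin gene AtCYP18-2 (AT2G36130). Cyclophilins are peptidyl-prolyl isomerases, and the series asks about transcripts and their splicing under heat in this mutant. Each genotype was sampled at 23 °C and after 1 h at 47 °C, with 3 samples in each of the 4 groups. No control is labelled as kept at 23 °C for the same hour, so the heat comparisons may also span that hour. Values in CPM are means ± SD with n = 3, and log2 fold changes are given ± SE.

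Chloroplast transcripts made up most of every library, with a share of 59.9 to 70.2% of reads. The transcript of psbA, the D1 protein of photosystem II, alone took 26.1 ± 5.72% of reads in WT control leaves and 34.1 ± 6.51% in heated WT leaves. In atcyp18-2 the share of psbA was 27.3 ± 4.73% without heat and 33.6 ± 5.95% after heat. Libraries held 9075387 to 12493977 reads, and 2572364 to 4348395 of these came from nuclear genes. Within every group the libraries also fell apart along 1 common component, which held 53.9% of the variance within groups. Negative scores on it were found in WT control replicates 1 and 2, atcyp18-2 control replicate 1, WT heat replicate 3 and atcyp18-2 heat replicate 2, and positive scores in the 7 other libraries. The heated groups of both genotypes thus had 1 library with a negative score each, whereas the control groups differed, with 2 such libraries in WT and 1 in atcyp18-2. In every group the share of psbA was lower in the libraries with a negative score (21.96 to 26.74%) than in the others (28.73 to 38.65%), so the group means of psbA also depend on these numbers. The sign of the score was set so that it rises with the share of psbA over all libraries. The direction of this relation is thus a convention, and only the separation within every group is a result.

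The mutated gene was reduced but not absent in atcyp18-2. AtCYP18-2 (AT2G36130) reached 5.97 ± 0.347 CPM in WT control leaves (62 to 99 reads per library) and 1.02 ± 0.0564 CPM in atcyp18-2 control leaves (11 to 13 reads). After heat it stood at 6.79 ± 1.10 CPM in WT (48 to 65 reads) and at 3.03 ± 1.01 CPM in atcyp18-2 (12 to 34 reads). Without heat the mutant was lower by a log2 fold change of -2.55 ± 0.25 (edgeR adjusted p = 0.00348). After heat the difference was -1.13 ± 0.24 and missed the threshold (adjusted p = 0.105). With TMM scaling, heat raised the transcript in atcyp18-2 by 1.59 ± 0.28 (adjusted p = 0.000817). In WT the change was 0.17 ± 0.22 (adjusted p = 0.615). The difference between these heat responses, 1.42 ± 0.35, did not pass either (adjusted p = 0.561). In replicates 1, 2 and 3 the mutant had 13, 13 and 11 reads without heat and 12, 34 and 17 after heat. The TMM factors of these libraries were 1.457, 1.178 and 1.169 without heat and 0.669, 0.906 and 0.678 after heat. The size of the rise in atcyp18-2 therefore depends on this scaling and on replicate 2 after heat. The counts do not show which part of the transcript the remaining reads cover.

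**Figure D1:**
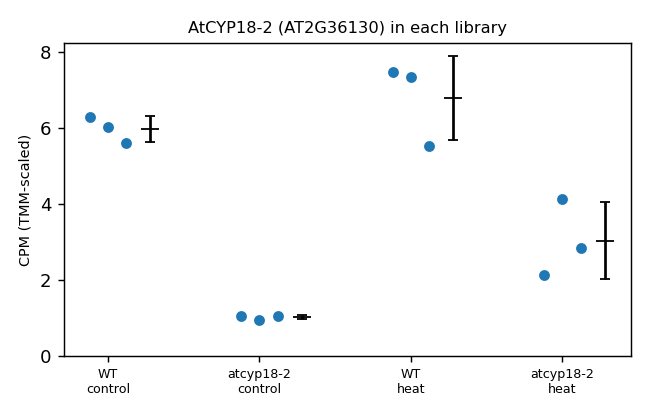
Level of AtCYP18-2 (AT2G36130) in CPM (vertical axis) in each of the 12 libraries, by group (horizontal axis). Points are libraries, and the bar beside them is the mean with its SD (n = 3). The 3 libraries of atcyp18-2 without heat lie near 1.02 CPM, below those of WT near 5.97 CPM.

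The first comparison asks what 1 h at 47 °C did to WT leaves. Small heat shock proteins, chaperones that bind unfolding proteins, showed the largest increases. HSP23.6-MITO (AT4G25200) had 0 reads in the 3 control libraries and 1874 ± 379.5 CPM after heat, at least 25460-fold higher. HSP17.6A (AT5G12030) reached 1199 ± 356.5 CPM from 1 read over the controls, a ratio of 54370 (interval 9757 to 2147000). HSP17.6II (AT5G12020) reached 907.3 ± 269 CPM with a ratio of 41050 (interval 7367 to 1622000). ATHSP22.0 (AT4G10250), AT1G53540 and HSP21 (AT4G27670) had 0 control reads and were at least 11200-fold, 10210-fold and 4289-fold higher. AT1G07400 rose by 11.76 ± 0.33 on the log2 scale to 1191 ± 60.9 CPM. Of the 17 fitted members of this list, 16 rose (16 adjusted over the list alone), with a median log2 fold change of 11.52, or 11.53 with genes at 0 reads set at their bound.

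Larger chaperones and the regulators of the heat response rose with them in WT. Among HSP70, HSP90, HSP100 and HSP60 chaperones 22 of 24 rose (22 adjusted over the list alone), by a median of 4.18. Hsp70b (AT1G16030) rose from 1.16 ± 0.299 to 4781 ± 325 CPM. HSP90.1 (AT5G52640) rose by 11.68 ± 0.53 and HSP70 (AT3G12580), the most abundant member, by 11.59 ± 0.29 to 5993 ± 646 CPM. Of the co-chaperones, 9 of 11 rose (9 adjusted over the list alone), with a median of 2.91. BAG6 (AT2G46240), a co-chaperone of the BAG family, rose by 11.25 ± 0.40, and the FK506-binding protein AT5G48570 by 10.52 ± 0.47. Among heat shock factors and related regulators 12 of 19 rose (12 adjusted over the list alone), with a median of 3.04. HSFA2 (AT2G26150), the heat-inducible transcription factor, rose by 9.50 ± 0.28 to 794.9 ± 41.8 CPM. AT-HSFA7B (AT3G63350) rose from 2 reads over the controls to 61.6 ± 15.6 CPM, a ratio of 1238 (interval 342.2 to 10230). The camera test gave adjusted p = 2.83e-31 for small heat shock proteins, 2.6e-29 for the larger chaperones, 8.22e-12 for co-chaperones and 6.6e-11 for heat shock factors. These calls held with an estimated correlation, at adjusted p = 0.017, 0.017, 0.0272 and 0.0285. Members of these families share near-identical stretches, and how the counting split such reads is not known.

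Dehydration, oxidative stress and protein folding lists also rose after heat in WT. Of the abscisic acid and dehydration list 14 of 22 rose (15 adjusted over the list alone), with a median of 1.56 and adjusted p = 1.02e-09 (0.0285 with an estimated correlation). Its median was 0.85 with library totals, under which 10 rose and 1 fell. GolS1 (AT2G47180), a galactinol synthase, rose by 6.60 ± 0.70 to 908.3 ± 116 CPM, and the dehydrin COR47 (AT1G20440) by 3.93 ± 0.69. Of the oxidative stress list 9 of 19 rose (12 adjusted over the list alone), with a median of 0.78 and adjusted p = 9.94e-07 (adjusted p = 0.075 with an estimated correlation), and with library totals the median was 0.02, with 6 higher and 2 lower. APX2 (AT3G09640), an ascorbate peroxidase, went from 0 reads to 186.1 ± 30.8 CPM, at least 2568-fold higher, and the zinc finger gene ZAT6 (AT5G04340) rose by 4.29 ± 0.32. The catalase CAT2 (AT4G35090) stood at 742.6 ± 74.7 CPM after heat, with a log2 fold change of 0.42 ± 0.17 (adjusted p = 0.0985) that turned to -0.34 when scaled by library totals. In the endoplasmic reticulum list 9 of 17 rose (9 adjusted over the list alone, with 1 lower), with a median of 0.65 and adjusted p = 0.000231 (adjusted p = 0.14 with an estimated correlation). This median turned to -0.06 with library totals, under which 4 rose and 2 fell. ATERDJ3A (AT3G08970) rose by 6.38 ± 0.35, BZIP28 (AT3G10800) by 2.21 ± 0.19 and BIP1 (AT5G28540) by 2.03 ± 0.21.

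Splicing factor genes were among those that rose in WT. Of 19 SR splicing factors 9 rose (12 adjusted over the list alone), with a median of 0.54 and adjusted p = 2.34e-07, which became adjusted p = 0.14 with an estimated correlation. The median turned to -0.19 with library totals, under which 4 rose and 1 fell. SR45a (AT1G07350) rose by 4.93 ± 0.20 to 361.4 ± 51.3 CPM and SR30 (AT1G09140) by 3.63 ± 0.20 to 147.2 ± 30.4 CPM. Of 28 other splicing factors 6 rose (8 adjusted over the list alone), among them EMB2770 (AT4G03430) by 3.14 ± 0.18 and AT5G64270 by 1.12 ± 0.27, and the list itself missed the threshold (adjusted p = 0.0656). Among the 27 other cyclophilins 4 rose (3 adjusted over the list alone), led by AT2G21130 at 3.84 ± 0.22 and AT1G01940 at 3.31 ± 0.42. The list was not called (adjusted p = 0.161), and ROC4 (AT3G62030), its most abundant member, had a log2 fold change of 0.37 ± 0.14 (adjusted p = 0.0801) that turned to -0.40 with library totals. With that scaling 2 other splicing factors rose and 7 fell, and 3 other cyclophilins rose and 7 fell, at list medians of -0.58 and -0.64 in place of 0.17 and 0.12.

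The glucosinolate, flavonoid, dividing cell and cell wall lists were lower as groups in heated WT leaves, and of these calls the one for dividing cells held with an estimated correlation. Of 21 glucosinolate genes 13 fell (14 adjusted over the list alone), with a median of -1.23 and adjusted p = 2.34e-07 (adjusted p = 0.14 with an estimated correlation). CYP79B2 (AT4G39950), which makes the precursor of indole glucosinolates, changed by -2.28 ± 0.36, its regulator MYB34 (AT5G60890) by -2.15 ± 0.35, and CYP83A1 (AT4G13770) by -1.23 ± 0.17. Of 9 flavonoid genes 4 fell (4 adjusted over the list alone), with a median of -1.39 and adjusted p = 0.00119 (adjusted p = 0.14 with an estimated correlation). UF3GT (AT5G54060) and DFR (AT5G42800) changed by -3.86 ± 0.74 and -2.79 ± 0.63, whereas TT4 (AT5G13930), chalcone synthase, was at -0.24 ± 0.26 (adjusted p = 0.536). Of 13 genes of dividing cells 8 fell (10 adjusted over the list alone), with a median of -0.89 and adjusted p = 4.56e-05 (0.017 with an estimated correlation). The cyclins CYCA1;1 (AT1G44110) and CYCB1;1 (AT4G37490) changed by -2.03 ± 0.33 and -1.48 ± 0.40, and TOPII (AT3G23890) by -0.51 ± 0.17. Of 14 expansins and xyloglucan endotransglucosylases, which loosen cell walls, 4 fell (9 adjusted over the list alone, with 1 higher), with a median of -0.74 and adjusted p = 0.00302 (adjusted p = 0.14 with an estimated correlation). EXPA1 (AT1G69530) fell from 140.2 ± 38.2 to 26.7 ± 3.91 CPM and EXPA4 (AT2G39700) by 1.89 ± 0.27 on the log2 scale, while XTH4 (AT2G06850) was at -0.19 ± 0.16 (adjusted p = 0.443). The medians of these 4 lists moved further down with library totals, to -2.0, -2.15, -1.63 and -1.49, with 19, 9, 12 and 12 genes lower.

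Among genes with a mean of at least 10 CPM, those with the largest decrease in WT included CGA1 (AT4G26150), a GATA factor of chloroplast development, at -2.61 ± 0.30, BBX32 (AT3G21150), a B-box protein, at -2.44 ± 0.24, and the glucosidase gene BGLU33 (AT2G32860) at -2.66 ± 0.53. AT2G30766, AT4G35270 and AT2G19650 changed by -2.48 ± 0.46, -2.31 ± 0.18 and -2.25 ± 0.25. AT3G28290 and AT3G28300, both annotated AT14A, were at -3.08 ± 0.80 each, but the pair is near-identical in sequence and their values are uncertain. Of 35 photosynthesis genes 8 rose and 1 fell, also when adjusted over the list alone, with a median of 0.37 and adjusted p = 0.00119 (adjusted p = 0.44 with an estimated correlation), and 1 rose and 16 fell with library totals, at a median of -0.39. LHB1B2 (AT2G34420) rose by 1.40 ± 0.28 and CAB3 (AT1G29910) by 0.98 ± 0.26, while CAB1 (AT1G29930), the most abundant, was at 0.43 ± 0.32 (adjusted p = 0.374). These light-harvesting genes have near-identical copies and are uncertain.

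The remaining lists were not called in WT. In the clock list 7 of 12 rose and 2 fell (7 and 3 adjusted over the list alone), with adjusted p = 0.0542. PRR7 (AT5G02810) and PRR5 (AT5G24470) rose by 2.78 ± 0.37 and 1.75 ± 0.36, and CCA1 (AT2G46830) was at -0.17 ± 0.29 (adjusted p = 0.71). Of 8 auxin response genes 2 rose and 1 fell, also adjusted over the list alone, with GH3.3 (AT2G23170) at 2.87 ± 0.21, WES1 (AT4G27260) at 2.70 ± 0.21 and IAA7 (AT3G23050) at 0.17 ± 0.14 (list adjusted p = 0.13). Of 20 jasmonate genes 2 rose (1 adjusted over the list alone), JAZ10 (AT5G13220) by 2.32 ± 0.43 and TIFY10B (AT1G74950) by 0.86 ± 0.29, and LOX2 (AT3G45140) was at -1.12 ± 0.53 (adjusted p = 0.148). This list's adjusted p was 0.886, with a median of -0.30 against an upward test direction. Of 19 salicylic acid genes 1 fell (0 adjusted over the list alone), PBS3 (AT5G13320) by 1.52 ± 0.47, with WRKY70 (AT3G56400) at 0.33 ± 0.52 (list adjusted p = 0.459). None of 9 rapid touch, cold and ethylene genes was called by edgeR, also adjusted over the list alone, and TCH3 (AT2G41100) was at 0.94 ± 0.52 (list adjusted p = 0.693). Markers of other cell types were measured as well. Of 4 guard cell genes KAT1 (AT5G46240) fell by 0.89 ± 0.30 (1 adjusted over the list alone; list adjusted p = 0.161). Of 2 fitted root genes PYK10 (AT3G09260) fell by 1.44 ± 0.34 from 38.4 ± 15.4 CPM (1 adjusted over the list alone), and no flower or seed gene was abundant enough to be fitted. With library totals the auxin median turned from 0.28 to -0.47, with 2 genes higher and 2 lower, while that of the clock list moved from 0.87 to 0.15, with 2 higher and 3 lower. Under that scaling 1 jasmonate gene rose and 7 fell, and 6 salicylic acid, 3 rapid touch, cold and ethylene, 3 guard cell and 2 root genes fell, with none higher.

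In all, 3911 of 16636 genes differed between heated and control WT leaves at a Benjamini-Hochberg adjusted p below 0.05 in the edgeR quasi-likelihood test, 2200 higher and 1711 lower. Without overlap between replicates were 37.4% of genes, where chance gives 10%. The directions are relative to the bulk of genes: with library totals alone the median gene moved by -0.77 and the split became 799 higher and 7500 lower. Fits by the sign of the library score, chosen after seeing the data, leave a single WT control or a single heated WT library. Their counts are therefore not set beside these.

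**Figure D2:**
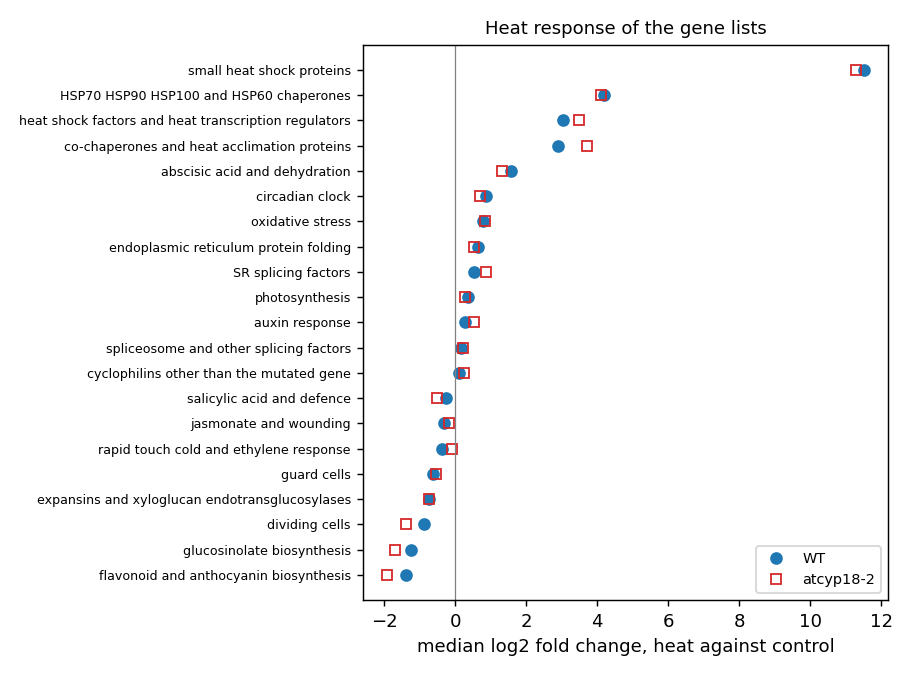
Median log2 fold change of heated against control leaves (horizontal axis) for the 21 gene lists with at least 3 fitted members (vertical axis). Filled circles are WT and open squares atcyp18-2, in each case over 3 against 3 libraries with TMM scaling. Small heat shock proteins stand at 11.52 and 11.30, and flavonoid, glucosinolate and dividing cell lists lie below 0 in both genotypes.

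The same question in atcyp18-2 gave a heat response led by the same families. HSP23.6-MITO (AT4G25200) reached 1942 ± 312 CPM, a ratio of 25480 over its control reads (interval 8717 to 123500). HSP17.6II (AT5G12020) and HSP17.6A (AT5G12030) had ratios of 46310 (interval 8310 to 1829000) and 28330 (interval 7842 to 234000), and ATHSP22.0 (AT4G10250) one of 35080 (interval 6296 to 1386000). AT1G53540, HSP21 (AT4G27670) and APX2 (AT3G09640) rose from 0 reads and were at least 10670-fold, 4687-fold and 4549-fold higher. AT1G07400, Hsp70b (AT1G16030), HSP70 (AT3G12580) and HSP90.1 (AT5G52640) rose by 12.35 ± 0.34, 12.06 ± 0.31, 11.41 ± 0.29 and 11.62 ± 0.53. Again 16 of 17 small heat shock proteins rose (16 adjusted over the list alone, median 11.30, also with genes at 0 reads at their bound), as did 22 of 24 larger chaperones (22 adjusted over the list alone, with 1 lower, median 4.10). Of co-chaperones 9 of 11 rose (9 adjusted over the list alone, median 3.71), including BAG6 (AT2G46240) by 11.45 ± 0.40 and Hop3 (AT4G12400) by 11.01 ± 0.60. Of heat shock factors 14 of 19 rose (14 adjusted over the list alone, median 3.50), with HSFA2 (AT2G26150) at 8.99 ± 0.27 and AT-HSFA7B (AT3G63350) at a ratio of 1488 (interval 266.3 to 58860). The camera test gave adjusted p = 1.98e-26, 1.95e-24, 2.55e-10 and 4.44e-11 for these lists, and 0.0212, 0.0186, 0.0329 and 0.0329 with an estimated correlation.

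Stress lists and the SR splicing factor list rose in atcyp18-2 too. In the abscisic acid list 14 of 22 rose (14 adjusted over the list alone), with a median of 1.31 and adjusted p = 2.28e-06 (adjusted p = 0.0794 with an estimated correlation). This median became 0.57 with library totals, under which 9 rose and 2 fell. The list was led by GolS1 (AT2G47180) at 6.82 ± 0.71 and COR47 (AT1G20440) at 4.44 ± 0.71. In the oxidative stress list 11 of 19 rose (11 adjusted over the list alone, with 1 lower), with a median of 0.85 and adjusted p = 3.26e-05 (adjusted p = 0.11 with an estimated correlation), and with library totals the median was 0.10, with 6 higher and 3 lower. ZAT6 (AT5G04340) rose by 4.11 ± 0.32, and CAT2 (AT4G35090) was at 0.38 ± 0.17 (adjusted p = 0.106), or -0.38 with library totals. Of 17 endoplasmic reticulum genes 8 rose (8 adjusted over the list alone, with 1 lower), with a median of 0.54, -0.24 with library totals (4 higher and 4 lower), and adjusted p = 0.00945 (adjusted p = 0.237 with an estimated correlation). ATERDJ3A (AT3G08970), BZIP28 (AT3G10800) and BIP1 (AT5G28540) rose by 6.82 ± 0.36, 2.43 ± 0.20 and 1.73 ± 0.21. Of 19 SR splicing factors 13 rose (13 adjusted over the list alone), with a median of 0.87 and adjusted p = 1.14e-06, which became adjusted p = 0.156 with an estimated correlation. The median became 0.11 with library totals, under which 5 rose and 4 fell. SR45a (AT1G07350) rose by 5.15 ± 0.20 and SR30 (AT1G09140) by 4.17 ± 0.20. Of 28 other splicing factors 10 rose (10 adjusted over the list alone), with EMB2770 (AT4G03430) at 2.76 ± 0.18, AT4G03120 at 1.43 ± 0.27 and AT5G64270 at 1.19 ± 0.27, and the list itself missed the threshold (adjusted p = 0.051). Of 27 other cyclophilins 5 rose and 2 fell, also adjusted over the list alone, with AT2G21130 at 3.61 ± 0.21, AT1G01940 at 3.43 ± 0.42 and ROC4 (AT3G62030) at 0.02 ± 0.14 (-0.75 with library totals; list adjusted p = 0.148). With library totals 3 other splicing factors rose and 7 fell, and 3 other cyclophilins rose and 8 fell, at list medians of -0.53 and -0.49 in place of 0.22 and 0.25.

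Among genes that fell in atcyp18-2, 16 of 21 glucosinolate genes passed (17 adjusted over the list alone), with a median of -1.69 and adjusted p = 3.11e-09 (adjusted p = 0.108 with an estimated correlation). GSTF11 (AT3G03190), CYP79B2 (AT4G39950) and CYP83A1 (AT4G13770) changed by -4.38 ± 0.51, -3.05 ± 0.40 and -1.74 ± 0.18. Of 9 flavonoid genes 8 fell (9 adjusted over the list alone), with a median of -1.91 and adjusted p = 3.26e-05 (adjusted p = 0.0783 with an estimated correlation). UF3GT (AT5G54060), DFR (AT5G42800) and TT4 (AT5G13930) changed by -3.74 ± 0.86, -3.10 ± 0.70 and -0.94 ± 0.26. Of 13 dividing cell genes 10 fell (12 adjusted over the list alone), with a median of -1.38 and adjusted p = 3.66e-07 (0.0132 with an estimated correlation). CYCA1;1 (AT1G44110), CYCB1;1 (AT4G37490) and TOPII (AT3G23890) changed by -3.10 ± 0.39, -2.75 ± 0.49 and -0.96 ± 0.18. Of 14 cell wall genes 7 fell and 1 rose, also adjusted over the list alone, with a median of -0.75 and adjusted p = 0.00831 (adjusted p = 0.172 with an estimated correlation). EXPA1 (AT1G69530) and EXPA11 (AT1G20190) changed by -2.47 ± 0.25 and -2.12 ± 0.43, and XTH4 (AT2G06850) was at -0.21 ± 0.16 (adjusted p = 0.349). The medians of the dividing cell and cell wall lists moved further down with library totals, to -2.13 and -1.53, with 13 and 11 genes lower. Among genes with a mean of at least 10 CPM, AT1G72910 (-3.02 ± 0.34), BBX32 (AT3G21150; -2.97 ± 0.27), AT2G19650 (-2.95 ± 0.27), AT1G06000 (-2.80 ± 0.37), AT4G35270 (-2.79 ± 0.20), AT5G54130 (-2.70 ± 0.28), AT5G42760 (-2.63 ± 0.28), AT1G06360 (-2.61 ± 0.24) and the cellulose synthase-like gene CSLD5 (AT1G02730; -2.58 ± 0.31) changed most.

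The other lists in atcyp18-2 were mixed. Of 35 photosynthesis genes 12 rose and 1 fell (13 and 2 adjusted over the list alone), with a median of 0.29 and adjusted p = 0.0189 (adjusted p = 0.593 with an estimated correlation), and 2 rose and 18 fell with library totals, at a median of -0.49. LHB1B2 (AT2G34420) and LHCA4 (AT3G47470) rose by 1.63 ± 0.28 and 1.06 ± 0.22, and CAB1 (AT1G29930) was at 0.15 ± 0.32 (-0.63 with library totals). Of 12 clock genes 5 rose and 2 fell (7 and 2 adjusted over the list alone; list adjusted p = 0.13), with PRR7 (AT5G02810) at 3.32 ± 0.38, LHY (AT1G01060) at -1.91 ± 0.13 and CCA1 (AT2G46830) at 0.28 ± 0.29. Of 8 auxin genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.0686), with WES1 (AT4G27260) at 3.31 ± 0.22, GH3.3 (AT2G23170) at 2.68 ± 0.22 and IAA7 (AT3G23050) at 0.44 ± 0.14 (-0.30 with library totals). Of 20 jasmonate genes 2 rose and 1 fell (1 and 0 adjusted over the list alone; list adjusted p = 0.794), with JAZ10 (AT5G13220) at 2.07 ± 0.42, VSP2 (AT5G24770) at -1.94 ± 0.69 and LOX2 (AT3G45140) at -1.42 ± 0.53 (adjusted p = 0.0571). Of 19 salicylic acid genes 2 fell (0 adjusted over the list alone; list adjusted p = 0.148), BGL2 (AT3G57260) by 2.23 ± 0.78 and PBS3 (AT5G13320) by 1.93 ± 0.55, and WRKY70 (AT3G56400) was at -0.73 ± 0.53 (adjusted p = 0.317). Of 9 rapid touch, cold and ethylene genes 1 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.586), with AT5G51190 at -2.30 ± 0.51, ERF5 (AT5G47230) at -1.88 ± 0.53 and TCH3 (AT2G41100) at 1.69 ± 0.52. None of 4 guard cell genes passed the edgeR test, also adjusted over the list alone (list adjusted p = 0.308), and of 2 root genes PYK10 (AT3G09260) fell by 1.04 ± 0.35 (1 adjusted over the list alone). With library totals the clock median turned from 0.71 to -0.03, with 1 gene higher and 2 lower, and the auxin median from 0.54 to -0.20, with 2 higher and 2 lower. Under that scaling 1 jasmonate gene rose and 6 fell, and 6 salicylic acid, 3 rapid touch, cold and ethylene, 3 guard cell and 2 root genes fell, with none higher.

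In total 5358 genes differed between heated and control leaves of atcyp18-2, 2812 higher and 2546 lower. Without overlap between replicates were 44.8% of genes. With library totals alone the split was 1010 higher and 7409 lower, at a median shift of -0.76. With the libraries of positive score only, 6541 genes were called, where both groups keep more than a single library. The libraries of negative score leave a single one in each of these groups.

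The heat responses of both genotypes were set side by side, with no control library in common. Hsp70b (AT1G16030), HSFA2 (AT2G26150), GolS1 (AT2G47180) and SR45a (AT1G07350) rose and CYP79B2 (AT4G39950), EXPA1 (AT1G69530) and BBX32 (AT3G21150) fell in both. In the same direction in both were 3190 genes, 1873 higher against 371.9 for independent lists and 1317 lower against 261.9. The Pearson correlation of the log2 fold changes across genes was 0.91, with a slope of 1.01 for atcyp18-2 on WT. Genes are not independent replicates, so this describes these libraries only. In opposite directions 2 genes were called. APR1 (AT4G04610), an enzyme of sulfate assimilation, changed by 1.15 ± 0.21 in WT and -0.73 ± 0.21 in atcyp18-2. CDEF1 (AT4G30140), a cutinase gene, changed by -0.83 ± 0.27 in WT and 1.02 ± 0.29 in atcyp18-2. Both were chosen after their values were seen, and the difference of their responses was not past the threshold (adjusted p = 0.298 and 0.499). The count of such genes was 6 without WT control replicate 3, 5 without WT heat replicate 3, 4 without atcyp18-2 control replicate 2, and 3 without WT control replicate 2 or atcyp18-2 heat replicate 3. It was 1 without WT control replicate 1, atcyp18-2 control replicate 1 or WT heat replicate 1 or 2, and 0 without atcyp18-2 control replicate 3 or atcyp18-2 heat replicate 2. With 1 surrogate variable it was 18.

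The next comparison asks what the mutation did without heat. Few genes differed. TPS8 (AT1G70290), of the trehalose-6-phosphate synthase family, stood at 33.1 ± 12.2 CPM in atcyp18-2 and 8.92 ± 2.30 CPM in WT, a log2 fold change of 1.88 ± 0.26 (adjusted p = 0.037). AT3G59940, a kelch repeat F-box gene, stood at 44.1 ± 3.73 against 15.1 ± 4.83 CPM, a change of 1.54 ± 0.22 (adjusted p = 0.037). AT1G80440, another kelch repeat F-box gene, was also called, at 4.24 ± 1.19 against 1.01 ± 0.342 CPM and 2.01 ± 0.27 (adjusted p = 0.037), and is named here because the count is small. The only gene called lower was AtCYP18-2 (AT2G36130) itself. The edgeR test called 4 genes, 3 higher and 1 lower, and 6.7% of genes had no overlap between replicates, where chance gives 10%. In the authors' deposited table this comparison holds 7 genes, 6 higher and 1 lower. All of these moved the same way here, and 3 of them were called.

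No member of a gene list was called in the mutant without heat. The photosynthesis list was higher as a group, with a median of 0.15 over 35 genes (adjusted p = 0.00122), a call that was lost with an estimated correlation (adjusted p = 0.854). The other 20 tested lists were not called, at adjusted p from 0.0731 for glucosinolate genes (median 0.14) to 0.991 for jasmonate genes (median 0.06). Medians were 0.13 for small heat shock proteins, 0.09 for SR splicing factors, -0.01 for other cyclophilins and 0.03 for dividing cells. Adjusted over the list alone, 2 clock genes were higher and 1 rapid touch, cold and ethylene gene was lower. The median and the direction of the test differed in sign for the jasmonate, cyclophilin, clock, dividing cell and guard cell lists, and the mean and the median for oxidative stress.

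Over genes, the log2 fold changes of this comparison had a Spearman coefficient of 0.39 with the loadings on the library component. No other comparison had a larger one. The coefficient was -0.23 for the difference of the heat response and 0.15 for heat in WT. For heat in atcyp18-2 it was 0.0, and for the mutant against WT after heat -0.02. Negative scores were held by 2 of 3 WT and 1 of 3 mutant libraries, and heat in WT has the same uneven split. DESeq2 called 25 genes. Fits by the sign of the score leave a single WT or a single mutant control, so they cannot be set beside the 4 genes called by edgeR. Without WT control replicate 2 the count rose to 10. Without WT control replicate 1, WT heat replicate 1 or 2, or atcyp18-2 heat replicate 1 or 3 it fell to 1, and without atcyp18-2 control replicate 3 to 0. Without WT control replicate 3 it was 3, all lower, and TPS8 (AT1G70290), AT3G59940 and AT1G80440 were not among them. AT3G59940 was also not called without atcyp18-2 control replicate 1 or 2, where 4 and 3 genes were, nor was AT1G80440 without the latter.

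The same question after heat gave more genes that differed. DIN10 (AT5G20250), a dark-inducible gene of the raffinose synthase family, was at 229.3 ± 18.2 CPM in the mutant and 74.4 ± 8.95 CPM in WT, a log2 fold change of 1.62 ± 0.15 (adjusted p = 0.00112). STP1 (AT1G11260), a hexose transporter, was at 204.8 ± 23.1 against 82.8 ± 6.94 CPM, or 1.31 ± 0.22 (adjusted p = 0.0316). The beta-xylosidase genes BXL2 (AT1G02640) and BXL1 (AT5G49360) were higher by 1.08 ± 0.18 and 1.06 ± 0.19. AT1G72416 showed the largest increase, with 117.2 ± 21.7 against 29.1 ± 2.83 CPM and 2.01 ± 0.20 (adjusted p = 0.0021). GASA1 (AT1G75750), a gibberellin-regulated gene, was higher by 1.43 ± 0.22, and AT3G59940, AT5G65480, AT4G27450 and AT3G47550 by 1.23 ± 0.21, 1.21 ± 0.14, 1.15 ± 0.19 and 1.11 ± 0.16. APX2 (AT3G09640) was the single called member of the oxidative stress list, at 347.6 ± 49.6 against 186.1 ± 30.8 CPM and 0.90 ± 0.16 (adjusted p = 0.0376), while CAT2 (AT4G35090) was at 0.00 ± 0.17.

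Other genes were lower in heated atcyp18-2 than in heated WT. NIA1 (AT1G77760), a nitrate reductase, was at 54.9 ± 9.21 CPM in the mutant and 130.1 ± 33.8 CPM in WT, a log2 fold change of -1.25 ± 0.19 (adjusted p = 0.0281). LHY (AT1G01060), a morning transcription factor of the clock, was at 53.1 ± 3.96 against 105.1 ± 2.07 CPM, or -0.99 ± 0.13 (adjusted p = 0.0105), while CCA1 (AT2G46830) was at 0.26 ± 0.29. PAL1 (AT2G37040), phenylalanine ammonia-lyase, was lower by a log2 fold change of -0.89 ± 0.16. Also lower were AT3G56360 at -1.62 ± 0.28, the largest decrease of a called gene here, AT1G55960 at -1.11 ± 0.15, the ion channel gene CNGC12 (AT2G46450) at -1.10 ± 0.19, UNE10 (AT4G00050) at -1.08 ± 0.16, AT4G25210 at -1.03 ± 0.18 and AT1G29660 at -0.88 ± 0.14.

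**Figure D3:**
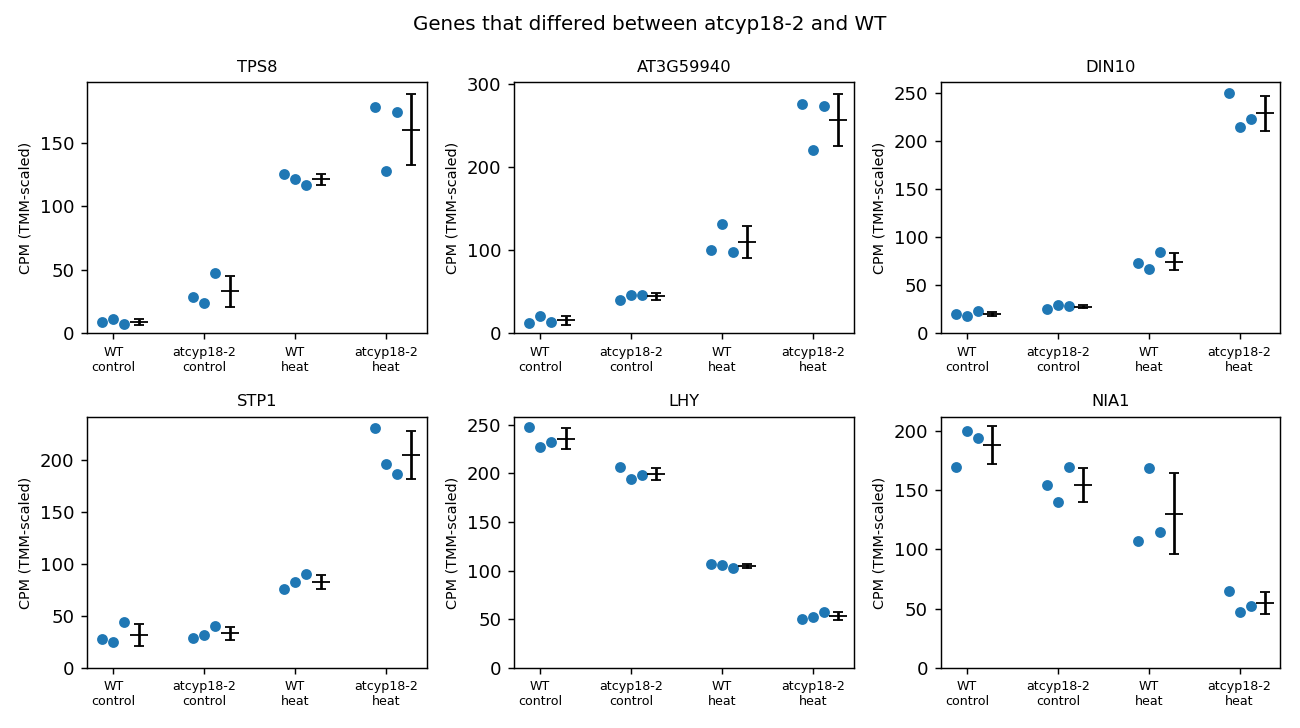
Levels of 6 genes in CPM (vertical axes) in each of the 12 libraries, by group (horizontal axes). Points are libraries, and the bar beside them is the mean with its SD (n = 3). TPS8 and AT3G59940 lie higher in atcyp18-2 without heat. DIN10 and STP1 lie higher after heat, at 229.3 and 204.8 CPM against 74.4 and 82.8 CPM in WT, and LHY and NIA1 lie lower.

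The genotypes were also compared in their gene lists after heat. None of 17 small heat shock proteins and none of 24 larger chaperones was called by edgeR, also adjusted over the list alone, with medians of 0.25 and 0.06 and adjusted p = 0.0616 and 0.617. HSP70 (AT3G12580) differed by 0.16 ± 0.18 and HSFA2 (AT2G26150) by -0.26 ± 0.18. Of the dividing cell list no single gene was called over all genes and 4 of 13 were lower adjusted over the list alone. The list was lower as a group, with a median of -0.72 (adjusted p = 6.84e-07, and 0.0103 with an estimated correlation). Its transcripts were scarce: TOPII (AT3G23890) was at 7.43 ± 0.456 CPM in the mutant and 10.8 ± 1.24 CPM in WT, and CYCB1;1 (AT4G37490) had 4 and 17 reads in all. Flavonoid genes were lower with a median of -0.62 (adjusted p = 0.00947) and glucosinolate genes with a median of -0.28 (adjusted p = 0.0069), and SR splicing factors were higher with a median of 0.20 (adjusted p = 0.0305). These 3 calls were lost with an estimated correlation, at adjusted p = 0.731, 0.827 and 0.827, and no member was called over all genes, against 3 flavonoid and 1 glucosinolate gene lower adjusted over the list alone. The other 17 tested lists were not called, at adjusted p of 0.0616 to 0.887. Adjusted over the list alone, 5 heat shock factors were higher and 2 lower, 2 endoplasmic reticulum genes lower, 3 cell wall genes higher, 1 oxidative stress gene higher, and 1 clock gene higher and 2 lower. The median and the direction of the test differed in sign for the cell wall and clock lists, and the median and the mean for oxidative stress.

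The edgeR test called 37 genes after heat, 27 higher and 10 lower in atcyp18-2, and 14.8% of genes had no overlap between replicates. The authors' deposited table holds 4 genes for this comparison, all higher and all called here: AT1G72416, AT1G66940, DIN10 (AT5G20250) and GASA1 (AT1G75750). DESeq2 called 218 genes, which included 36 of the 37, and 555 were called with the libraries of positive score, which included all 37. Both fits hold libraries from which the 37 were called, so this overlap was largely set beforehand and does not check them. The libraries of negative score leave a single heated one of each genotype and cannot check them either. A fit of only the 6 heated libraries called 1. With library totals 2 genes were higher and 4 lower. The count fell to 2 without WT heat replicate 1 or atcyp18-2 heat replicate 1, to 4 without atcyp18-2 heat replicate 2, and to 5 without WT heat replicate 2 or atcyp18-2 heat replicate 3. It fell to 6 without atcyp18-2 control replicate 2, 9 without atcyp18-2 control replicate 3, 17 without atcyp18-2 control replicate 1, 18 without WT control replicate 2 and 21 without WT heat replicate 3.

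The last comparison asks whether the heat response itself differed between the genotypes. The dividing cell, flavonoid and glucosinolate lists had a lower heat response in atcyp18-2 than in WT. Dividing cell genes differed by a median of -0.65 (adjusted p = 2.38e-05), with a median heat response of -0.89 in WT and -1.38 in atcyp18-2. This call held with an estimated correlation (adjusted p = 0.0231) and with fry (0.0175). Flavonoid genes differed by -0.70 (adjusted p = 0.0091) and glucosinolate genes by -0.39 (adjusted p = 8.18e-05). Both calls were lost with an estimated correlation, at adjusted p = 0.722 and 0.808. Adjusted over the list alone, 0 dividing cell, 2 flavonoid, 3 glucosinolate and 1 clock gene had a lower response and 1 heat shock factor a higher one. The other 18 tested lists were not called, at adjusted p of 0.104 to 0.982, among them small heat shock proteins with a median of 0.11, SR splicing factors with 0.15 and other cyclophilins with 0.03. For the larger chaperones the median was -0.05, the mean 0.02 and the test direction upward.

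No single gene differed in its heat response in the edgeR test, with 0 called and 912 at an unadjusted p below 0.05. DESeq2 called 30 genes, 15 in each direction. Fits by the sign of the library score leave at least one group with a single library and are not compared here. Between conditions, the effect of the mutation had a Pearson correlation of 0.10 across genes, and 27 of the 37 genes called after heat had the same sign without heat. The share of all genes with the same sign was not computed, so the 27 cannot be weighed against it.

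**Figure D4:**
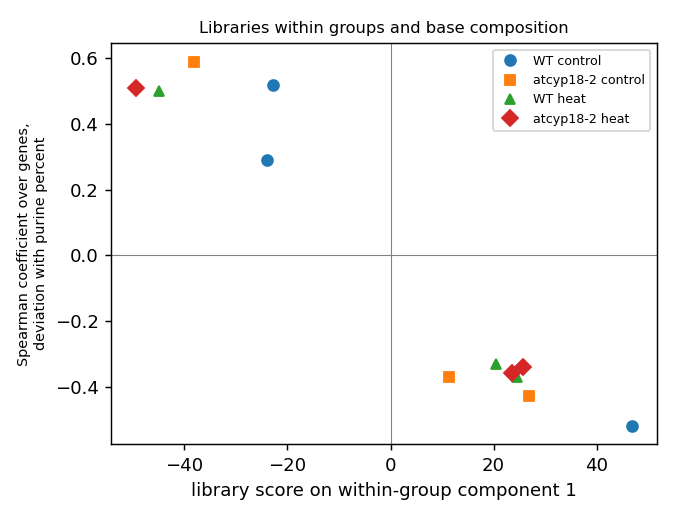
Score of each of the 12 libraries on the within-group component (horizontal axis) against the Spearman coefficient, over genes, of the library's deviation from its group mean with the purine percent of the transcript (vertical axis). Symbols are the 4 groups. The 5 libraries with a negative score have coefficients of 0.29 to 0.59 and the 7 with a positive score coefficients of -0.52 to -0.33.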

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

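The tests of the dividing cell list without heat and of the library component were chosen after the result had been seen, and that of 25 other cell division genes was set before their values were seen.

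The heat response differed between the genotypes in 3 gene lists, by a camera test of the difference itself. Dividing cell genes had a median difference of -0.65 on the log2 scale, atcyp18-2 minus WT, with 12 of 13 genes below 0. Flavonoid genes had a median difference of -0.70 and glucosinolate genes one of -0.39. These last calls were lost with an estimated correlation, at adjusted p = 0.722 and 0.808, and no explanation was tested for them.

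For the dividing cell list the reads were few: over 3 libraries CYCA1;1 (AT1G44110) had 217 reads in WT control, 196 in atcyp18-2 control, 28 in heated WT and 9 in heated atcyp18-2 leaves. A smaller number of dividing cells in atcyp18-2 before heat would have lowered the list without heat, and its median there was 0.03. But the list was flagged for a difference from which the value without heat is subtracted. A low value there was thus unlikely from the start, and its absence decides little. A fit of all 12 libraries with 1 surrogate variable kept 82% of the difference (-0.53). But the list was flagged in these same libraries, from which the surrogate variable was also estimated. Both heated groups also had 1 library with a negative score, so this does not exclude the library component. In the libraries with a positive and a negative score the difference was -0.73 and -0.50, but both rest on a single library in at least 1 group and decide nothing. A lower level of cell division transcripts in heated atcyp18-2 may extend beyond the list: 25 other cell division genes, listed without looking at their values, had a median of -0.58 after heat, with 18 of 25 below 0 (camera p = 0.045 with an estimated correlation, limma). The difference of their heat response, -0.37, missed the threshold (camera p = 0.111 with an estimated correlation, limma), and whether the pattern is biological stays open. Their median after heat was -0.05 with a negative score, which is 1 library against 1 and decides nothing.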

How the results depend on the processing

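The transcript choices, the subtracted read, the surrogate variable and the fits by library score were chosen after seeing the data. Counts are given for heat in WT, heat in atcyp18-2, the mutant against WT without heat, the mutant against WT after heat, the difference of the heat response, and genes shared by both heat responses, and the cause of the changes was not tested unless named. At an adjusted p below 0.01 the counts were 2094, 3232, 1 and 3, with 1755 shared. At an adjusted p below 0.05 and an absolute log2 fold change of at least 1 they were 2450 and 3372, 23 after heat, and 1919 shared. DESeq2 gave 25 without heat, 218 after heat and 30 for the difference. Library totals gave 8299, 8419, 0 and 6, with 6880 shared, and no filter on low counts gave 24 after heat. The filter at 10 CPM gave 2273, 2994 and 59 (after heat) among fewer genes, with 2004 shared. A fit of only the groups compared, with fewer samples, gave 1 without heat and 1 after heat. Without organelle genes 7 were called without heat.

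With 1 surrogate variable the counts were 7293, 8620, 63, 1321 and 211, with 5982 shared. In the libraries with a positive score 41, 555 and 98 genes were called in the last 3 comparisons, and with a negative score 60 after heat. In these fits lone samples of a group are assumed to vary like the others. Leaving out 1 library each gave 2648 to 4114, 4219 to 5656, 0 to 10, 2 to 39 and 0 to 0 genes, with 2335 to 3135 shared. The replicate block gave 1 without heat, 3 after heat and 0 for the difference. Of 18 pairs with the same replicate number 7 had a correlation over 0.1 (from -0.65 to 0.51), and 2 of 12 libraries correlated best with their own number. The numbers thus did not follow the main differences between libraries. These correlations still contained the library component, so a weaker pairing beneath it could not be seen. Without a block, camera called 13, 13, 1, 4 and 3 lists in the 5 comparisons, with an estimated correlation 6, 5, 0, 1 and 1, and fry 0 without heat, 1 after heat and 1 for the difference. With the surrogate variable it called 2 without heat and 7 after heat.

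Of the named genes, library totals turned CAT2 to -0.34 in WT and -0.38 in atcyp18-2, ROC4 to -0.40 and -0.75, and in atcyp18-2 CAB1 to -0.63 and IAA7 to -0.30, a scaling that moves the median of all genes down. Over the named genes, 72 values in heat in WT, 57 in heat in atcyp18-2, 27 without heat and 224 after heat lost the threshold under an alternative, and 1710, 1852, 644 and 923 kept their side of it. Depth limits what can be said of the dividing cell genes: CYCB1;1 had 4 reads over the 3 libraries of heated atcyp18-2.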

Other observations

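The tests of base composition, transcript length and the library component were chosen after the result had been seen, and those of 17 other sugar-repressed genes, of organelle genes and of other splits of the samples were set before.

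Several genes higher in atcyp18-2 are known to be repressed by sugar or induced in the dark. A set of 8 such genes, chosen after their values were seen, holds TPS8 (AT1G70290), AT3G59940, DIN10 (AT5G20250), STP1 (AT1G11260), AT4G27450, AILP1 (AT5G19140), BXL2 (AT1G02640) and BXL1 (AT5G49360). Their median log2 fold change, mutant against WT, was 1.12 after heat, where 7 were called, and 0.41 without heat, where 2 were called. From control to heated leaves the same genes moved by a median of 1.78 in WT and 2.53 in atcyp18-2. AILP1 (AT5G19140) reached 188.1 ± 26.1 CPM in heated atcyp18-2 and 99.5 ± 3.76 CPM in heated WT, from 40.1 ± 1.29 and 31.3 ± 5.04 CPM without heat (SD, n = 3).

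A lower sugar supply in atcyp18-2 may account for this pattern, as a hypothesis. The 17 other sugar-repressed genes, listed without looking at their values, had a median of 0.45 after heat, with 15 of 17 above 0 and none called alone by edgeR (camera p = 0.0239 with an estimated correlation, limma). Without heat their median was 0.18, with 16 of 17 above 0 (camera p = 0.0266 with an estimated correlation, limma). The difference of the heat response was 0.29 (camera p = 0.338 with an estimated correlation, limma). In the libraries with a positive and a negative score these medians were 0.56 and 0.22 after heat, 0.45 and 0.11 without heat, and 0.08 and 0.05 for the difference, but all except the 0.56 rest on a single library in at least 1 group and decide nothing. For the 8 genes, the libraries with a positive score, 2 heated ones of each genotype, kept 108.7% of the median after heat (1.22). A fit of all 12 libraries with 1 surrogate variable kept 99.2% (1.11). But the genes were chosen from these libraries, and both heated groups had 1 library with a negative score. The outcome could thus hardly differ, and it does not exclude the library component. Sugar was not measured, and a difference in the time of harvest, which also moves such genes, stays open. After heat LHY (AT1G01060) was at -0.99 ± 0.13 in the mutant against WT and CCA1 (AT2G46830) was at 0.26 ± 0.29 (SE). The clock list then went both ways, with a median of 0.04, 6 of 12 genes above 0 and 6 below (fry mixed adjusted p = 1.02e-06, limma). The mixed test also responds to a few members, and 1 gene, LHY, was called over all genes. As a whole the list was not called (camera p = 0.762 with an estimated correlation, limma). Without heat its median was -0.01 (fry mixed adjusted p = 0.944, limma).

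The component that separates libraries within every group held 53.9% of the variance within groups, against 9.3% for the next. Base composition of the transcripts is a candidate explanation: over 16465 nuclear genes the loading had a Spearman coefficient of -0.60 with purine percent and 0.24 with GC percent, although genes are not independent replicates. Transcript length is argued against by a coefficient of 0.01. Without organelle genes the first component held 53.5% of the variance. That fit still had 16446 genes, against 16636 with them, so a large drop could hardly occur. This leaves organelle genes as a source undecided, and the share of psbA moved with the score in every group. Purine percent, GC percent and length together held 45.0% of the rank variance of the loadings, and what made the libraries differ stays open, since the labels name no batch. No biological explanation was tested.

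Other splits of the samples were tried for each comparison. For heat in WT and heat in atcyp18-2 the real splits gave 3911 and 5358 genes and the highest other split 0, and for the mutant against WT the real splits gave 4 without heat and 37 after heat against 1 and 0. With 1 of 10 splits as large in each case, 10 splits are too few for a share under 0.05. For the difference of the heat response the genotypes were reassigned within each treatment, with 100 of 200 splits drawn. The real split gave 0 genes, a count that any split reaches, so these splits do not test it. The highest other split gave 4570 genes, and 2 more gave 4502 and 4528. These 3 splits put the 3 control libraries with a negative score together with 3 heated libraries of positive score, which points to the structure of the samples along the library component. The 11 other drawn splits with these controls, each with a heated library of negative score beside them, gave 0 genes.

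Assembled transcripts were used only for genes without an annotated transcript and in an alternative chosen after seeing the data. For each nuclear gene the transcript with the highest total, assembled or annotated, was set against the one used here. Summed over genes, the excess of the former was 1.08 ± 0.39% of its reads in WT control and 1.13 ± 0.24% in atcyp18-2 control leaves. It was 1.49 ± 0.40% in heated WT and 1.33 ± 0.41% in heated atcyp18-2 leaves (SD, n = 3). Assembled transcripts with a lower total than the annotated one add nothing here, so reads that only they hold are not covered.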
